A study of Mus musculus with 8 samples.

How the data were processed

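The series holds 2 single-cell libraries of medulloblastoma cells and 6 RNA-seq libraries of sorted astrocytes, all from mice deficient in Patched 1, the receptor that holds the Hedgehog pathway off. Per the labels, the single-cell libraries are 1 primary tumour and 1 relapsed tumour taken at 3 weeks, and the astrocyte libraries are 3 of stroma A and 3 of stroma B. The design text says that astrocytes of primary and relapsed tumours were compared, but no label says which stroma is which, so the groups keep the names stroma A and stroma B and no value is read as primary or relapsed. The description of the relapsed single-cell library names a primary tumour, against its title and its source label. The title and source were followed. The sort was by flow cytometry and the tissue was dissociated with papain, per the labels.

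Per the labels' protocols, cells for the single-cell libraries were partitioned on a Chromium Controller, and the deposited matrices hold whole-number UMI counts per gene and cell. The submitters' processing notes name Cell Ranger, STAR, Seurat and the mm10 build, with no role, order or version. The bulk values were deposited as whole-number read counts per gene symbol and as FPKM, both as the authors made them, and the counting tool, the annotation and the strand setting are not given in the sources used here. The columns of stroma A replicate 2 carry a further number after the title of the sample and were matched to it on their shared start, an assumed match that no other title met. The bulk libraries carry the same extraction text as the single-cell libraries, so their own library preparation is unclear from the labels. No cell annotation by the authors was used here. Without a stated strand, reads of a gene and of an antisense or overlapping partner cannot be told apart.

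The bulk counts covered 20608 gene symbols, of which 639 were 0 in all libraries, and summed to between 6718165 and 11798735 reads per library. Genes were filtered with filterByExpr by group at its default settings, which left 14176, scaled with TMM factors and tested for stroma B against stroma A with edgeR's quasi-likelihood F-test (edgeR 4.0.16, R 4.3.3) without covariates. Adjusted p-values are Benjamini-Hochberg over all genes tested, with a threshold of 0.05 and no fold threshold. The standard error of a log2 fold change is its size divided by the square root of the F statistic. Levels are CPM values scaled with the TMM factors, as mean ± SD of 3 libraries.

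Gene lists and cell type markers were fixed before the data were examined. All 25 gene lists and 12 of the 18 marker lists, those with at least 5 measured members, were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted within each family. Estimated correlation and fry, which asks whether a list moves 1 way without comparing it with other genes, were alternatives. Coordinates and gene types came from GENCODE M21 on mm10, matched by symbol.

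Cells with at least 500 detected genes and at most 10% mitochondrial UMIs passed, 9094 of 9164 barcodes in the primary and 7839 of 7852 in the relapsed library. Doublets were scored per library with Scrublet in scanpy 1.11.5 at an expected 6%. Its automatic threshold marked 561 relapsed cells, which were removed, and 0 primary cells. A caller that marks under 0.5% was taken as failed, so the 6% of primary cells with the highest scores were removed, 546 in number. This left 8548 primary and 7278 relapsed cells. Both libraries were clustered together on log-normalised UMIs (10000 per cell, 2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 1, leidenalg 0.10.2), without batch integration.

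Clusters were named from the fixed markers. Outside the granule lineage, a name needed at least 3 markers at 4-fold or more over all other cells, at 20 CPM or more, and with a UMI in 20% of the cluster's cells. Clusters with markers of more than 1 class were divided again. The granule neuron lineage, which includes the tumour cells, was divided into precursor, cycling and differentiating classes. This naming rule was set after the data had been seen. Of 2 versions tried, the first read pooled levels alone and is kept as an added alternative. The thresholds, the joining of microglia with macrophages, the joint granule lineage, and the limit of 0.65 of the median gene number below which a cluster stayed unnamed were also chosen after seeing the data. Within the cycling class, 1 cluster rested on 2 raised markers and a pair of others on 1 marker each with leading cell cycle genes. Most large granule clusters held cells of almost 1 library alone. The 3 granule classes are therefore not compared in size between libraries, only the joint lineage.

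With 1 single-cell library per group there is no test, and cells are not replicates. Shares carry exact Clopper-Pearson 95% intervals and summed UMIs carry exact Poisson 95% intervals, which cover counting error only (scipy 1.17.1). Log2 ratios are relapsed over primary with 0.5 added to each sum. A fold against 0 UMIs is given as at least the fold against a floor of 3 counts summed over the class. Gene lists were described by the percentile of their median ratio among 10000 random lists of like size and expression, over genes with at least 20 UMIs in the class and lists with at least 5 such members. Random genes were drawn independently, so members that vary together are not allowed for and a percentile is not a test. Shares of cells with a UMI were compared after thinning each cell to 2000 UMIs.

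Genes were named by a rule fixed in advance. In bulk it took the 10 largest and 10 smallest log2 fold changes among genes past the threshold, with a mean log2 CPM of at least 1 and no overlap between groups. It also took up to 4 passing members per list and 13 genes whatever their result. In single cells it took, in each class with at least 50 cells in both libraries, the 10 highest and 10 lowest ratios among genes with at least 100 UMIs and 20 CPM, plus the same 13 genes. Xist, Y-linked, haemoglobin, mitochondrial and predicted genes were left out of the rule. Xist and 4 Y-linked genes, Prm1 in bulk, and pituitary hormone genes are reported outside it, chosen after their values were seen. Not all genes that the rule takes are printed.

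The code was tested on simulated counts with known answers. For stroma B against stroma A, over 14176 genes, the test recovered 4% of 50 genes changed by a log2 fold of 1, 42% at 2, 76% at 3 and 86% at 4, with 3 false calls among 107. Genes were drawn independently here, without differences between libraries that many genes share. These rates therefore need not hold for the real libraries, whose cell makeup differed. Simulated single-cell sums over 11595 genes gave all 50 genes at each of the log2 ratios −2, −1, 1 and 2 within 0.5 of the truth. These sums had the depth of whole libraries, counting noise alone and genes with at least 100 primary UMIs. They therefore do not show how well ratios are recovered in small classes. Planted lists lay at percentiles 100 and 0, and 1 of 25 unchanged lists lay outside the middle 95% of random lists.

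Alternatives fixed in advance were DESeq2 size factors in edgeR, no count filter, each library left out, the pair of libraries that share a number in their titles left out, DESeq2 1.42.0 on all 19969 genes with a count, limma-trend on log2(FPKM + 1) or log2(FPKM + 0.1) of the deposited FPKM with at least 1 FPKM in 3 libraries or unfiltered, estimated correlation, fry, other cell filters (200 genes and 20% or 1000 genes and 5%), doublets kept, Leiden resolutions 0.5 and 2, scaling within libraries, thinning, and sums without the 50 most abundant genes. Added after seeing the data were a fit of 1 against 3 libraries, blocks for Y-linked and for Prm1 reads, and the first naming rule.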

Results

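Single-cell RNA was profiled in 1 primary and 1 relapsed medulloblastoma of Patched 1 deficient mice, a model of tumours driven by Sonic hedgehog that arise from cerebellar granule neuron precursors. The primary library held 9164 barcodes and 56332247 UMIs, with a median of 5404 UMIs and 2130.5 genes per cell. The relapsed library, taken at 3 weeks, held 7852 barcodes and 69403567 UMIs, with medians of 7230.0 UMIs and 2505 genes. RNA of sorted astrocytes was sequenced in 3 libraries of stroma A (9434960, 6718165 and 8657692 reads) and 3 of stroma B (8812991, 11798735 and 11170367 reads). Per the design text, the single cells address the makeup of primary and relapsed tumours, and the sorted libraries address gene expression of astrocytes in the 2 settings. The labels do not tie stroma A or stroma B to either setting.

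Ptch1, the gene made deficient in these mice, was detected in every library. Its level was 143, 70.3 and 111 CPM in the stroma A libraries and 541, 516 and 118 in the stroma B libraries. In single cells of the granule lineage it was 144 CPM (140–147) in the primary and 152 (148–155) in the relapsed library. Counts over a whole gene or its 3' end do not show whether the deleted part is missing, so these values check nothing about the genotype.

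The sorted libraries of stroma B carried more RNA of dividing cells than those of stroma A. Mki67, a marker of cycling cells, rose from 638 ± 60.6 to 2026 ± 279 CPM (SD, n = 3 in each group), with a log2 fold change of 1.67 (SE 0.24, edgeR adjusted p = 0.0471). Smc4, a condensin subunit that compacts mitotic chromosomes, rose from 119 ± 3.96 to 436 ± 17.6. Egfr, a growth factor receptor of neural progenitors and glia (chromosome 11, 16752203–16918158 on mm10), rose from 21.3 ± 6.92 to 167 ± 36.1, a log2 fold change of 2.96 (SE 0.32, edgeR adjusted p = 0.0383). Lower in stroma B were Cntn6, an adhesion molecule of the contactin family (chromosome 6, 104492790–104863406), from 37.2 ± 4.26 to 1.87 ± 0.882, and Vwf, the von Willebrand factor of endothelial cells, from 112 ± 75.4 to 7.52 ± 1.48.

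Of 14176 genes tested, 3095 had an unadjusted p under 0.05 in edgeR and 94 passed, 55 higher and 39 lower in stroma B. All 94 had groups that did not overlap, as did 27.2% of all genes tested, against 10% by chance. Among the genes with the largest rise were Sdpr (log2 fold change 3.11), which shapes caveolae, Egfr (2.96), the spindle protein Psrc1 (2.31), the transcription factor Lhx2 (2.27) and Sncaip (2.25). Esco2 (2.09), an acetyltransferase of cohesin, Prr11 (2.05), the condensin subunit Smc2 (1.92) and Dbf4 (1.90), the activator of the replication kinase Cdc7, followed. Among those with the largest fall were Hs3st1 (−5.06), a heparan sulfate sulfotransferase, Scel (−4.81), Dcaf12l2 (−4.66), the glutathione transferase Gsto1 (−4.35) and Cntn6 (−4.32). Vwf (−3.89), the ubiquitin ligase Trim25 (−3.78), the actin regulator Cobl (−3.48) and Pcnxl2 (−3.10) followed. Adjusted p-values of these genes in edgeR lay between 0.0383 and 0.0499. The count rested on single libraries: it was 0 without any of stroma A replicates 1, 2 and 3 or stroma B replicates 1 and 2 (between 2067 and 3781 genes at an unadjusted p under 0.05) and 1342 without stroma B replicate 3. It was also 0 with both libraries of the shared number left out, and with a block for Y-linked or for Prm1 reads (1563, 2731 and 3089 genes at an unadjusted p under 0.05), the blocks chosen after the data were seen. DESeq2, run without that count filter on 19969 genes, gave 1728, 45.5% of them higher in stroma B, against 58.5% in edgeR. Without the filter edgeR gave 227 genes, so test and filter both differ between these counts.

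The cell cycle lists moved together. All 42 members of the G2/M list were fitted higher in stroma B, with a median log2 fold change of 1.47 (camera adjusted p = 5.81e-49). Over all genes 21 of them rose, and 41 did when adjusted over the list alone. Its members with the smallest p were Smc4 (log2 fold change 1.87), Hmmr (1.66), the kinetochore motor Cenpe (1.70) and the spindle motor Kif11 (1.86). All 32 members of the G1/S list were fitted higher as well (median 1.19, camera adjusted p = 1.63e-21), with 1 gene, the ribonucleotide reductase subunit Rrm2 (1.77), past the threshold over all genes and 29 adjusted over the list alone. With an estimated correlation the calls were lost, at an adjusted p of 0.170 for G2/M and 0.378 for G1/S. In fry G2/M passed (adjusted p = 0.0125) and G1/S did not (adjusted p = 0.0918). In the plot of list levels, the G2/M median was 5.41, 5.32 and 5.31 log2 CPM in stroma A and 7.02, 6.50 and 6.73 in stroma B.

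**Figure D1:**
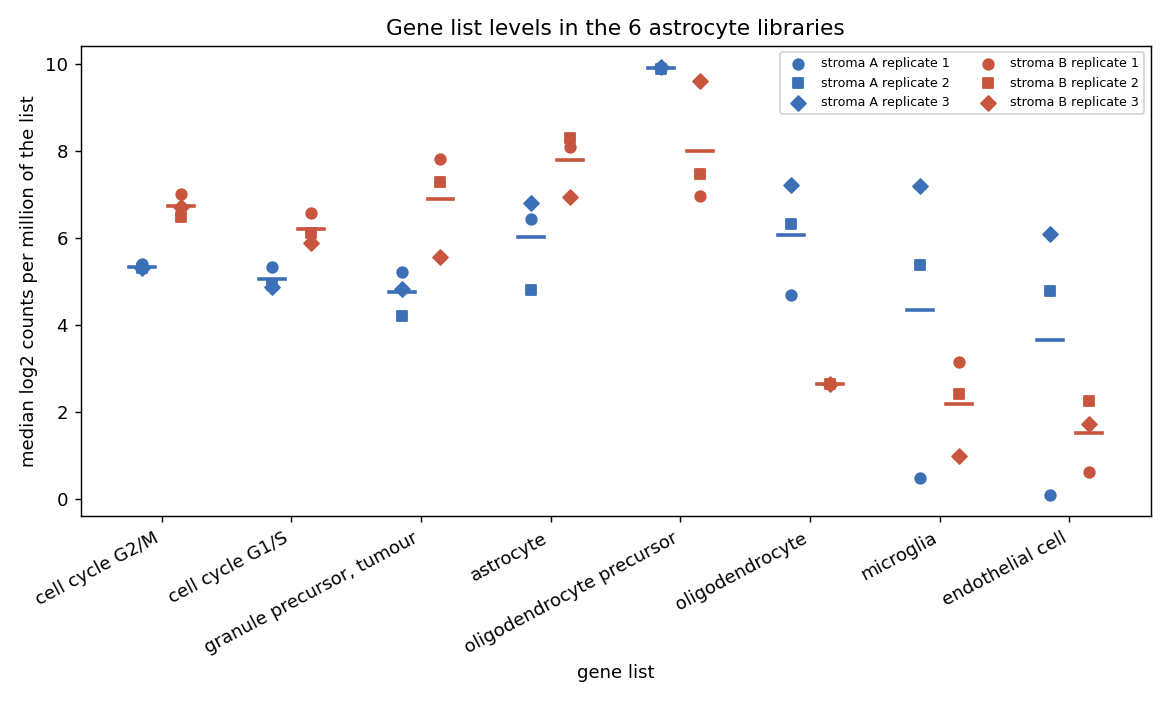
Median log2 CPM (vertical axis) of 8 fixed gene lists (horizontal axis) in each library of stroma A (blue) and stroma B (red), with bars at group means and symbols for replicates. The G2/M list lay between 5.31 and 5.41 in stroma A and between 6.50 and 7.02 in stroma B, whereas oligodendrocyte precursor markers lay between 9.90 and 9.93 in stroma A and between 6.97 and 9.61 in stroma B.

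Genes of the granule precursor and tumour program and of the Hedgehog pathway had higher fitted values in stroma B. The granule precursor and tumour list had a median log2 fold change of 2.27 (camera adjusted p = 4.26e-12), with 22 of 23 members fitted higher, 0 past the threshold over all genes and 19 adjusted over the list alone. Its levels overlapped between groups, with medians of 6.0, 4.46 and 4.93 log2 CPM in stroma A and 8.22, 7.50 and 5.84 in stroma B. With an estimated correlation its adjusted p was 0.546. The Hedgehog list had a median of 1.70 (camera adjusted p = 0.000225), with 0 of 19 past the threshold over all genes and 9 adjusted over the list alone, and an adjusted p of 0.378 with an estimated correlation. Gli1, a Hedgehog target and effector, was at 227.8 and 157 CPM in stroma B replicates 1 and 2, 20.5 in replicate 3, and between 15.3 and 30.8 in stroma A (edgeR adjusted p = 0.133). Atoh1, which marks granule precursors, had a log2 fold change of 2.61 (edgeR adjusted p = 0.207). Ptch1 had one of 1.86 (edgeR adjusted p = 0.143).

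Astrocyte genes lay higher in stroma B without passing one by one. Astrocyte markers had medians of 6.45, 4.81 and 6.82 log2 CPM in stroma A and 8.09, 8.31 and 6.96 in stroma B. Oligodendrocyte precursor markers had 9.91, 9.90 and 9.93 against 6.97, 7.48 and 9.61. Astrocyte markers thus lay above them only in stroma B replicates 1 and 2, although levels of different lists do not measure cell numbers. Which glial cells were captured was not separated from changes within astrocytes. The astrocyte identity list had a median log2 fold change of 1.07 (camera adjusted p = 1.14e-05; adjusted p = 0.550 with an estimated correlation), with 0 of 24 past the threshold over all genes and 9 adjusted over the list alone. Gfap, the intermediate filament of astrocytes, was at 87.8 ± 54.8 in stroma A and 581 ± 453 in stroma B (SD, n = 3 each; edgeR adjusted p = 0.152), and in stroma B replicate 3 it was 81.4. Log2 fold changes were 2.58 for the water channel gene Aqp4 (edgeR adjusted p = 0.150), 2.44 for the glutamate transporter gene Slc1a3 (0.119), 2.14 for Aldh1l1 (0.146) and 2.90 for Sox9 (0.0864). S100b had −1.08 (edgeR adjusted p = 0.184). The neural stem and progenitor list, which holds Egfr, had a median of 0.96 (camera adjusted p = 5.48e-05; adjusted p = 0.378 with an estimated correlation), with 1 of 18 past the threshold over all genes and 9 adjusted over the list alone. Shh (log2 fold change −1.10), Bmp4 (−1.27) and Id1 (0.99) did not pass, at edgeR adjusted p-values of 0.518, 0.525 and 0.504. Without stroma B replicate 3, Gfap (log2 fold change 3.27), Slc1a3 (2.87), Sox9 (3.32), Ptch1 (2.31), Gli1 (3.25) and Bmp4 (−3.67) passed in edgeR. In DESeq2 Gfap, Aqp4, Slc1a3, Aldh1l1, Sox9, Ptch1, Gli1 and Atoh1 passed with all 6 libraries.

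Immune genes were fitted lower in stroma B, but not in all pairs of libraries. Interferon genes had medians of 1.25, 3.34 and 4.85 log2 CPM in stroma A and 2.76, 2.47 and 0.40 in stroma B, inflammatory genes 0.86, 3.93 and 5.0 against 2.41, 2.60 and 0.50, and antigen presentation genes 2.72, 4.74 and 5.65 against 2.90, 2.05 and 3.21. Microglia (median log2 fold change −3.65), macrophage (−3.71) and endothelial markers (−3.40) were lower as well. The antigen presentation list had a median log2 fold change of −2.11 (camera adjusted p = 3.68e-07; adjusted p = 0.546 with an estimated correlation), with 0 of its 16 members fitted higher, 0 past the threshold over all genes and 14 adjusted over the list alone. Interferon response genes had a median of −1.55 (camera adjusted p = 2.10e-05; adjusted p = 0.659 with an estimated correlation) and inflammatory cytokine and chemokine genes −1.61 (camera adjusted p = 0.00940; adjusted p = 0.776 with an estimated correlation). Smaller medians passed for ribosomal protein genes (0.40, camera adjusted p = 0.0181), p53 response genes (0.34, camera adjusted p = 0.0306) and cholesterol synthesis genes (−0.37, camera adjusted p = 0.0256). With an estimated correlation their adjusted p-values were 0.776, 0.550 and 0.774, and library medians of the ribosomal and p53 lists overlapped between groups. Calls that ended when 1 library was left out were the inflammatory list (adjusted p = 0.257 without stroma A replicate 3 and 0.175 without stroma B replicate 3), the ribosomal list (0.0655 without stroma A replicate 3 and 0.939 without stroma B replicate 1), the p53 list (up to 0.197, without stroma B replicate 3) and the cholesterol list (up to 0.415, without stroma A replicate 1). With both libraries of the shared number left out the ribosomal list changed direction, the inflammatory list ceased to pass (camera adjusted p = 0.382) and 5 lists newly passed. The blocks were chosen after the data were seen. With the Prm1 block the inflammatory list ceased to pass (camera adjusted p = 0.0825), and the pan-reactive (0.0437) and A2 reactive lists (0.0282) passed. With the Y block the growth factor list passed (camera adjusted p = 0.0349). A fit of 1 against 3 libraries left out the stroma A libraries with most myeloid and vascular genes, after their values were seen. In it the interferon list ceased to pass and the inflammatory list changed direction. It kept only stroma A replicate 1, which had the lowest stroma A medians of both lists, so the choice of libraries favoured this outcome. Its spread came from stroma B alone. In all, 12 of 25 lists passed camera, 0 with an estimated correlation and 1 in fry. The 13 that did not pass were the pan-reactive (camera adjusted p = 0.126), A1 (0.396) and A2 (0.190) reactive astrocyte lists, mature granule neuron (0.598), BMP (0.592), Notch (0.643; its median of 0.07 and mean of −0.02 differ in sign), Wnt (0.166), TGF-beta (0.282), growth factor (0.117), extracellular matrix (0.253), glycolysis and hypoxia (0.368), oxidative phosphorylation (0.592) and immediate early and dissociation stress genes (0.297). The pan-reactive list passed without stroma A replicate 3 (camera adjusted p = 0.00118) and without stroma B replicate 3 (0.00142), and 7 others passed without at least 1 library.

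Markers of other cell types moved with the groups and differed in size between libraries. Granule precursor and tumour markers had a median log2 fold change of 2.48 (camera adjusted p = 6.56e-10), cycling cell markers 1.51 (5.77e-23), astrocyte markers 1.92 (7.28e-07) and differentiating granule neuron markers 0.84 (0.00838). Oligodendrocyte markers had −3.86 (camera adjusted p = 2.67e-10), macrophage markers −3.71 (0.00679), microglia markers −3.65 and endothelial markers −3.40 (both 0.00169), and oligodendrocyte precursor markers −1.48 (5.84e-05). With an estimated correlation the adjusted p-values of these 9 lists lay between 0.0901 and 0.470. Pericyte (camera adjusted p = 0.238), fibroblast (0.202) and ependymal (0.399) markers did not pass. Pdgfra, the receptor that marks oligodendrocyte precursors, was at 7606, 4285 and 3988 CPM in stroma A and 805, 485 and 3607 in stroma B. Microglia markers had medians of 0.49, 5.39 and 7.21 log2 CPM in stroma A and 3.14, 2.41 and 1.00 in stroma B, so stroma A replicate 1 lay apart from the other 2. Library medians of the macrophage, endothelial and differentiating granule neuron markers overlapped between groups as well. Over all genes, stroma B replicate 3 correlated best with stroma A replicate 1 (r = 0.937, across genes, which are not independent replicates).

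The cells of both tumours were mostly granule lineage cells, the lineage of the tumour. They made up 87.1% of 8548 kept cells (86.4–87.8) in the primary and 93.9% of 7278 (93.3–94.4) in the relapsed library. Astrocyte-like cells were 0.632% (0.475–0.823) and 0.893% (0.690–1.14), with intervals that overlap and cover counting error only. Oligodendrocyte precursor-like cells were 2.19% (1.89–2.52) in the primary and 0.453% (0.312–0.636) in the relapsed library, and microglia and macrophage-like cells 2.32% (2.01–2.66) and 0.412% (0.278–0.588). Endothelial-like cells were 18 and 6, pericyte-like cells 5 and 13, and fibroblast-like cells 8 and 20. No cell was named a T or NK cell, B cell, neutrophil, oligodendrocyte, ependymal cell, inhibitory neuron, unipolar brush cell or erythrocyte, 0 of 8548 and 0 of 7278, with exact upper limits of 0.0431% and 0.0507%. Unnamed cells were 7.41% and 3.83%. The labels describe a sort, which can set such shares, and with the stricter cell filter of 1000 genes the astrocyte-like share was 0.286% and 0.494%, the oligodendrocyte precursor-like share 0.680% (0.505–0.895) and 0.436% (0.294–0.621), with overlapping intervals, and the relapsed myeloid share 0.232%. The oligodendrocyte precursor-like cells came mainly from cluster 14 in the primary and from cluster 15 in the relapsed library, where a first version of the naming rule left 0.0275%.

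**Figure D2:**
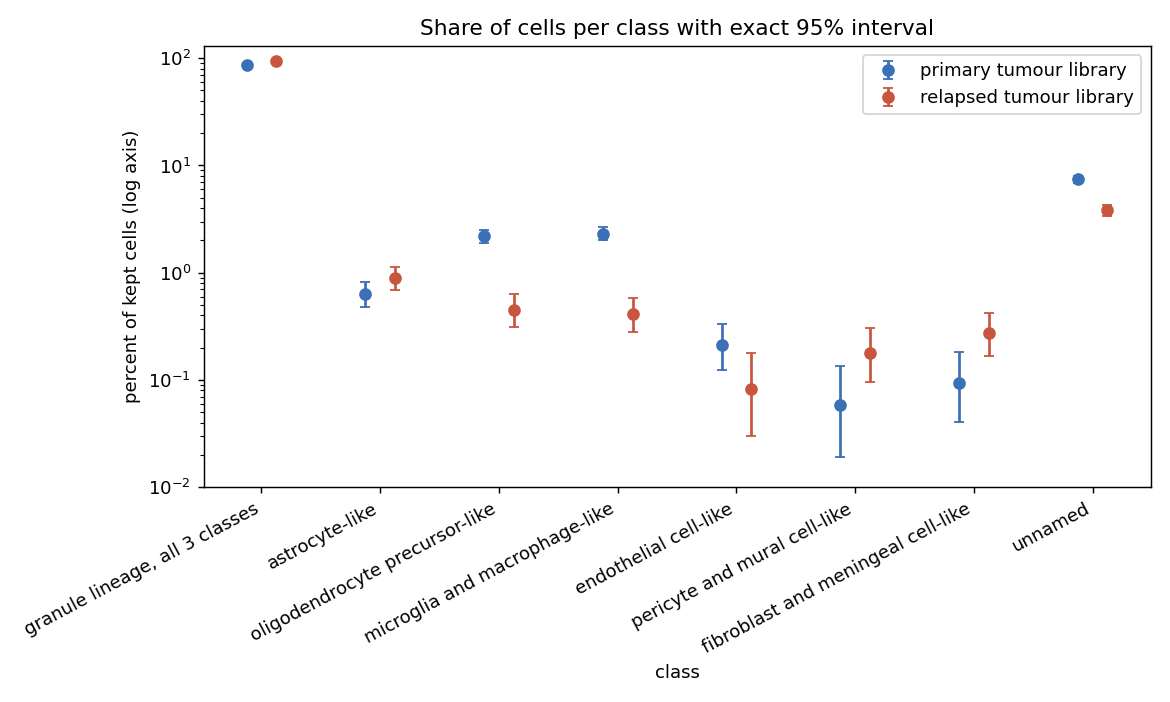
Share of kept cells (vertical axis, percent, log axis) per class (horizontal axis) in the primary (blue) and relapsed (red) library, with exact 95% intervals that cover counting error only. Oligodendrocyte precursor-like cells were 2.19% in the primary and 0.453% in the relapsed library, and granule lineage cells 87.1% and 93.9%.

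Astrocyte-like cells of the relapsed tumour held more RNA of glycolysis and hypoxia genes and less of Hedgehog targets than those of the primary tumour. There were 54 such cells in the primary library, mainly in sub-clusters 1 (35 cells) and 3 (13) of cluster 15, and 65 in the relapsed library, mainly in its sub-clusters 0 (37), 4 (13) and 3 (12). Ptch1, itself a Hedgehog target, was at 576 CPM (492–671) in the primary and 93.6 (76.4–113) in the relapsed cells, a log2 ratio of −2.62. Gli1 was at 62.5 (37.0–98.7) and 7.20 (3.11–14.2), from 18 and 8 UMIs. The Hedgehog list had a median log2 ratio of −1.40, below 10000 random lists (percentile 0), and 10 of 11 measured members were lower. The glycolysis and hypoxia list had a median of 1.53 (percentile 100), with 22 of 24 members higher. In the same cells immediate early and dissociation stress genes were higher as well (median 0.91, percentile 100, 18 of 22 members) and ribosomal protein genes lower (−0.31, percentile 0), so handling of the tissue and RNA quality were not separated from the change. Granule precursor and tumour genes fell alongside (−1.28, percentile 0, 16 of 18 members lower), and as 8 of 15 granule markers are also on the Hedgehog list, less RNA of tumour cells was not separated from it either.

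In these astrocyte-like cells Gfap was at 1954 CPM (1796–2122) in the primary and 2409 (2319–2502) in the relapsed library, a log2 ratio of 0.30 that was −0.61 with the stricter cell filter. Log2 ratios were −0.83 for Aqp4, 1.18 for S100b, −0.52 for Slc1a3, 1.54 for Aldh1l1, −0.33 for Sox9, −0.62 for Id1, −0.22 for Atoh1 and 0.53 for Mki67, the last from 3 and 19 UMIs. Shh and Bmp4 had 0 UMIs in both, with upper limits of 12.8 CPM in the primary and 3.32 in the relapsed cells. The genes with the lowest ratios were Wif1 (−6.95), a secreted Wnt inhibitor, Fxyd1 (−3.13), Chchd10 (−2.86), Rsrp1 (−2.77), Ptch1 and Nxf1 (−2.40). Neat1 (−1.93), the Notch target Hes5 (−1.91), Zic4 (−1.90) and Tgfb2 (−1.86) followed. The genes with the highest ratios included the smooth muscle actin gene Acta2 (5.42), the oxidative folding gene Ero1l (5.32), Glycam1 (4.13), the alarmin Il33 (3.97), the hypoxia-induced gene Bnip3 (3.81) and Tubb6 (3.79). Prm1 (at least 1068-fold higher), Ccl5 (at least 11.2-fold), Prl (at least 9.68-fold) and Gh (at least 8.73-fold) had 0 primary UMIs. Prl and Gh are pituitary hormone genes, and in the relapsed library they were at 129 and 81.6 CPM in differentiating granule cells too. Gh was higher still in the precursor class of that library. That library also held 120 unnamed cells with Prl at 179959 and Gh at 155927 CPM, and its unnamed cells with few detected genes had 109 and 72.8.

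Of 23 lists measured in the astrocyte-like cells, 6 lay above and 5 below the middle 95% of random lists, which do not allow for members that vary together. Above it, besides glycolysis and hypoxia and immediate early and dissociation stress genes, were A2 reactive genes (median 0.99, percentile 99.9), growth factors (0.78, percentile 100), G2/M genes (0.70, percentile 100) and extracellular matrix (0.44, percentile 99.7). Below it, besides the Hedgehog, ribosomal and granule precursor lists, were Wnt genes (−1.09, percentile 0.1) and BMP genes (−0.62, percentile 1.27). The astrocyte identity list was at 0.13 (percentile 71.2). The relapsed astrocyte-like cells were deeper, with a median of 16563 UMIs against 4669. After thinning each cell to 2000 UMIs, which left out 0 cells, Ptch1 had a UMI in 46.3% (32.6–60.4) of primary and 13.8% (6.53–24.7) of relapsed astrocyte-like cells, against 64.8% and 66.2% unthinned. Microglia and macrophage-like cells had one in 3.54% (1.43–7.15) and 0% (upper limit 11.6) after thinning. Gfap had one in 68.5% and 75.4% (92.6% and 96.9% unthinned), against 3.03% and 3.33% of the microglia and macrophage-like cells, which should lack it and had median depths of 6208.5 and 11145.5 UMIs.

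Granule lineage cells of the relapsed tumour had like levels of Hedgehog targets and held less RNA of immune genes. The Hedgehog list had a median log2 ratio of −0.20 (percentile 14.1), with Ptch1 at 0.08 and Gli1 at 37.0 CPM (35.3–38.8) in the primary and 32.3 (30.8–33.8) in the relapsed library. Atoh1 was at 166 (162–169) and 239 (235–243), and Mki67 at 117 (114–121) and 106 (103–109). Inflammatory genes had a median log2 ratio of −1.92 (percentile 0), antigen presentation genes −1.58 (percentile 0.04) and interferon genes −1.57 (percentile 0), with microglia and macrophage-like cells at 2.32% and 0.412% of the same libraries. RNA of those cells carried into granule droplets was not separated from a change in the granule cells. Astrocyte identity genes had −0.90 (percentile 0), with Gfap at 61.4 and 26.5 CPM and Aqp4 at 2.79 and 0.635. Of 25 lists, 4 lay above and 6 below the middle 95% of random lists. Above it were G2/M (0.21, percentile 99.98), glycolysis and hypoxia (0.36, percentile 99.95), cholesterol synthesis (0.34, percentile 99.97) and p53 response genes (0.23, percentile 98.9). Below it were also pan-reactive astrocyte (−1.21, percentile 0.11) and granule precursor and tumour genes (−0.25, percentile 0.84). Other log2 ratios were 0.81 for S100b, 0.39 for Slc1a3, −0.69 for Aldh1l1, 0.17 for Sox9 and −0.92 for Id1. Bmp4 had 14 and 8 UMIs and Shh 0 in both.

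Within the granule lineage, different clusters held each class in the 2 libraries, so values belong to those clusters as much as to the tumours. In the precursor class (cluster 4 in the primary, clusters 3, 6 and 11 in the relapsed library) the G2/M list had a median log2 ratio of 2.33, G1/S 1.32, and Mki67 was at 19.4 and 56.0 CPM, a log2 ratio of 1.52 that was −0.11 with doublets kept. In the cycling class (clusters 1, 2 and 10 against 0 and 12) G2/M had 0.45 and G1/S −0.37. In the differentiating class (clusters 7 and 8 against 5) they had −0.44 and −0.32.

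Some genes were close to absent from the granule lineage of 1 tumour. The tumours also differed in sex-linked RNA. Granule lineage cells had Xist at 1766 CPM in the primary and 1.27 in the relapsed library, and Y-linked genes at 0.0432 and 198. Sex and animal were therefore not separated from relapse in the ratios of granule lineage or astrocyte-like cells. The naming rule left out Xist but not Tsix. Hoxb2, a hindbrain patterning gene, was at least 379-fold lower in relapsed precursor-class cells, with 369 UMIs in the primary and 0 in the relapsed library, and Hoxb3os at least 371-fold. Mndal (log2 ratio −9.14), Tsix (−8.80), the antisense partner of Xist, Helt (−7.08), Ren1 (−6.87), Mgl2 (−5.39), Meis2 (−5.05), Gsto1 (−4.86) and RP24-402O2.2 (−4.41) followed. Higher in the relapsed precursor class were Gh (at least 1131-fold), Prm1 (at least 125-fold), BC023719 (at least 114-fold), Prl (7.79), Abhd12b (7.13), the actin-binding gene Pdlim3 (4.49), the kinetochore gene Casc5 (3.77), the mitotic phosphatase gene Cdc25c (3.70, but −0.30 with doublets kept), Tlx3 (3.59) and Ak1 (3.48). The differentiating class had Ifi203 at least 48.6-fold lower and Clic6 (−4.50), Crabp1 (−4.35) and Gdpd3 (−3.91) among the lowest, besides Mndal, Hoxb2, Ren1, Meis2, Tsix and Mgl2. Its highest, besides Gh, BC023719, Prl and Abhd12b, were Ccl27a (3.56), Mid1 (3.49), Pcp4 (3.25), Ifitm10 (3.22), Ret (3.13) and Etaa1os (3.08). The cycling class added Lyz2 (−4.04), Fitm1 (−3.51) and Rbm45 (−3.47) to the lowest and Mtfr2 (3.71), Ssu2 (3.39) and Mmp2 (2.97) to the highest. Gh and Prl were also present in unnamed cells of the relapsed library, as given above. RNA carried over from those cells was not separated from RNA made in granule cells. Mndal and Ifi203 belong to a family of near-identical genes, so their values are uncertain.

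The relapsed tumour held cells with Y-linked RNA and cells with Xist, the RNA of an inactive X chromosome, and among named classes these mostly fell in different ones. Its granule lineage had 4 Y-linked genes at a summed 198 CPM (195–202) and Xist at 1.27. Its astrocyte-like cells had Y-linked genes at 168 CPM (145–194) and Xist at 75.6, the latter as 84 UMIs in 3 cells, and 57 of 65 cells had a Y-linked UMI. Its oligodendrocyte precursor-like cells had Y-linked genes at 172 CPM (134–217) and 0 UMIs of Xist. In contrast, its microglia and macrophage-like cells had Y-linked genes at 11.1 CPM (3.02–28.3) and Xist at 1013, and endothelial-like (13.6 and 2098), pericyte-like (33.0 and 1476) and fibroblast-like cells (16.6 and 1265) were alike. Unnamed relapsed cells carried both, with Y-linked genes at 36.4 CPM and Xist at 810. In the primary tumour, the granule lineage had Y-linked genes at 0.0432 CPM and Xist at 1766, and 0 of 54 astrocyte-like cells had a Y-linked UMI.

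Prm1, a protamine gene normally read in sperm precursors, was seen in the same relapsed glial cells. It was at 11124 CPM in the relapsed astrocyte-like cells, where 98.5% of cells had one, and 4129 in the relapsed oligodendrocyte precursor-like cells, where all 33 did. Granule lineage cells had 61.2 CPM, and 16.9% of them had a UMI at a median of 6949 UMIs per cell. By class they had 84.5 CPM in cycling, 50.6 in precursor and 10.8 in differentiating cells. Microglia and macrophage-like cells had 11.1 CPM, and 13.3% of them had a UMI at a median of 11145.5 UMIs per cell. The primary library had 0 in all classes. Some reporter constructs end in a protamine sequence, and no transgene sequence was used here, so UMIs and reads of the gene and of such a construct cannot be told apart. Among the sorted libraries, Prm1 had 2322 reads in stroma A replicate 1, 1 in each of replicates 2 and 3, and 0, 2541 and 5272 in stroma B.

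**Figure D3:**
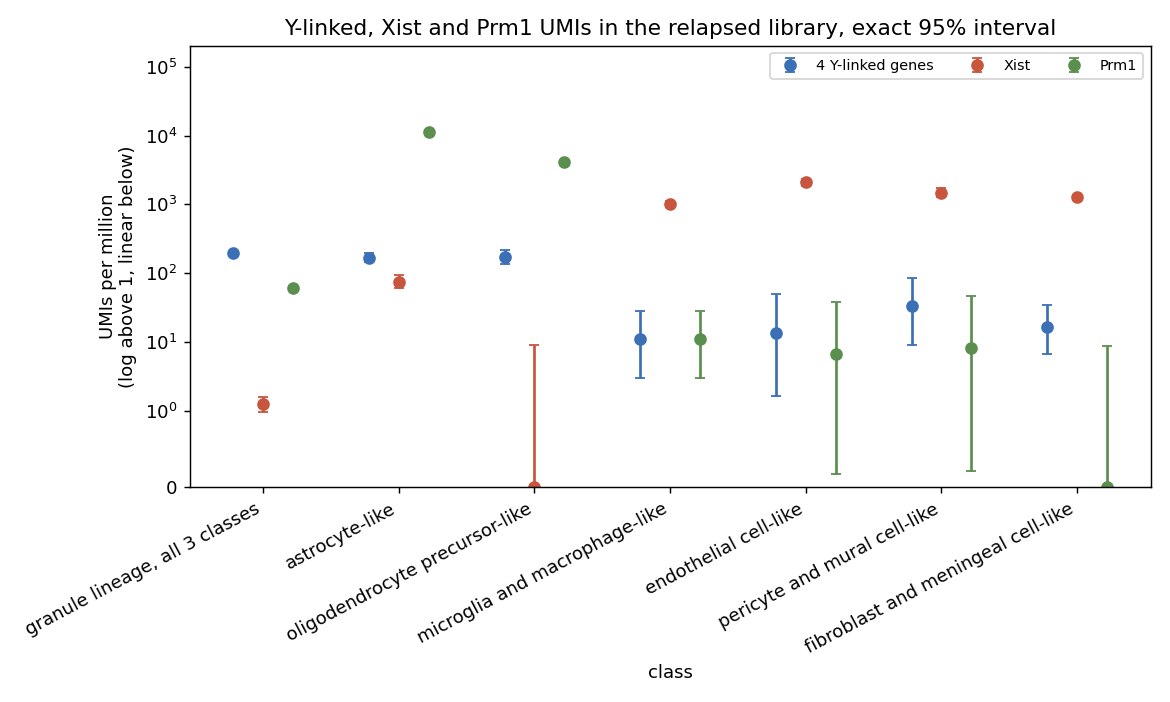
CPM (vertical axis, log above 1 and linear below) of 4 Y-linked genes (blue), Xist (red) and Prm1 (green) per class (horizontal axis) of the relapsed library, with exact 95% intervals. Y-linked UMIs were at 198 in the granule lineage, 168 in astrocyte-like and 11.1 in microglia and macrophage-like cells.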

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

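All tests in this part were chosen after the results had been seen. The relapsed library held 120 unnamed cells, 1.65% of its kept cells (exact interval 1.37–1.97), led by the pituitary hormone genes Prl and Gh at 179959 and 155927 CPM, against 0 of 8548 primary cells (exact upper limit 0.0431%). They stood out as a signal in cells that no comparison used. Unnamed cells with few detected genes were 7.17% of the primary and 2.18% of the relapsed library. In the deposited FPKM, features with NONCODE identifiers, which have no match in the counts, held between 63.2% and 82.2% of the summed values of a library.

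The median level of the G2/M cell cycle list was higher in all 3 stroma B libraries than in all 3 of stroma A. Fewer cells of other types in stroma B would raise the markers of each type that stayed, and this stays open. Median log2 fold changes were −3.86 for oligodendrocyte, −3.65 for microglia, −3.71 for macrophage and −3.40 for endothelial markers. Astrocyte markers, those of the type sorted for, had 1.92. Oligodendrocyte precursor markers, with a median of −1.48, cannot decide it, because they may belong to the cells that became fewer. Tumour cells carried into the sorted stroma B libraries may add to the pattern, because the granule precursor and tumour markers had a median of 2.48, above the 1.47 of the G2/M list, and among them Sfrp1 was at 1281, 555 and 181 CPM in stroma B (112, 49.6 and 59.0 in stroma A) and Zic1 at 731, 552 and 136 (125, 46.4 and 83.9), although Ccnd1 was not higher there (613, 726 and 1445 against 1402, 1140 and 970). Of the 15 markers, 8 are also on the Hedgehog list, 0 are on the cell cycle lists, and 13 were at 20 CPM or more in primary astrocyte-like cells, and in stroma B replicate 3 their median (5.56 log2 CPM) was close to the 5.22 of stroma A replicate 1 while G2/M was at 6.73 against 5.41. A sort for astrocytes would remove such cells if complete, and more division among the astrocytes of stroma B stays open as an untested biological explanation.

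In the relapsed library, Y-linked UMIs occurred in astrocyte-like cells at 15.2 times the level of microglia and macrophage-like cells (interval 5.84–56.4), which free RNA in the droplets, spread alike over cell types, does not give. Doublets with tumour cells would bring granule markers in the same proportion, but the median ratio of 12 granule markers, astrocyte-like over granule lineage, was 0.188 against 0.847 for the Y-linked genes. Cells of male and female animals in 1 library would put the 2 signals in different cells. In 5115 of 6832 relapsed granule lineage cells Y-linked UMIs occurred without Xist. In 27 of 30 microglia and macrophage-like cells Xist occurred without a Y-linked UMI, and in 0 the reverse. Over the library 2.27% of cells had Xist alone, including 102 unnamed cells, whereas 51 unnamed cells had Y-linked UMIs alone. That share could speak only against a mix. In the relapsed granule lineage 6 cells had Xist alone, so in these named classes the 2 signals mostly fell in different cells, as a mix would give. By which route cells of both sexes would have entered the library stays open, since the labels do not say whether the tumour grew in a host of the other sex. A candidate explanation is that most astrocyte-like and oligodendrocyte precursor-like cells share the sex, and so possibly the origin, of the tumour cells, whereas the myeloid and vascular cells belong to another animal, but sex alone does not show descent. In the primary library tumour and other cells alike carried Xist, so the same comparison cannot be made there.

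The 94 genes and 12 lists that passed between stroma B and stroma A were set against all 10 splits of the 6 libraries into 3 and 3. For genes, 1 split reached the real count, the real one itself, and the highest other gave 1 gene. For lists, 5 splits reached the real count, and the highest other gave 16. With 10 splits the share cannot be under 0.1, which is too few to judge the gene count. For lists, mixed groupings gave as many or more, so the number of lists passing does not set the real grouping apart.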

How the results depend on the processing

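Fits with 1 against 3 libraries, with blocks for Y-linked or Prm1 reads, and with the first naming rule were chosen after seeing the data, and all other alternatives before. The number of genes passing between stroma B and stroma A (94) changed most: it ranged from 0 to 1342 with 1 library left out. It was 0 in edgeR with 2 against 2 libraries, 0 with 1 against 3, 0 with the Y block, 0 with the Prm1 block, and 0 in limma on unfiltered FPKM (1563, 1137, 2731, 3089 and 4136 genes at an unadjusted p under 0.05). It was 227 without a count filter (91 shared), 1728 in DESeq2 (94 shared), which was also run without that filter, 285 in limma on log2(FPKM + 1) (75 shared), 152 with 0.1 (62 shared), and 91 with other size factors. The median log2 fold change of the genes tested was −0.03 in edgeR (14176 genes), −0.15 in edgeR and −0.26 in DESeq2 without a filter (19969 each), and 0.24 and 0.30 on FPKM (13160). Fewer libraries leave fewer degrees of freedom, and otherwise the cause was not tested. Of the 12 lists passing, 0 passed with an estimated correlation and 1 in fry, and with 1 library left out the number ranged from 10 to 13. No paired analysis was possible because the titles of the groups share only 1 number.

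Reversed directions occurred in lists that did not pass, except the inflammatory and ribosomal lists, and the cause was not tested. With 1 library left out, adjusted p-values ranged from 0.105 to 0.996 for A1 reactive (reversed without stroma A replicate 3, and 0.888 without stroma B replicate 3), 0.0128 to 0.791 for A2 reactive (reversed without stroma A replicate 1, passing without stroma A replicate 3), 0.364 to 0.996 for mature granule neuron (reversed without stroma A replicate 3 or stroma B replicate 1), and 0.186 to 0.953 for Notch (reversed without stroma A replicate 2). They ranged from 0.0187 (without stroma A replicate 1) to 0.996 for TGF-beta (reversed without stroma B replicate 3, 0.863), 0.00735 (without stroma B replicate 2) to 0.996 for extracellular matrix (reversed without stroma A replicate 3), 0.156 to 0.903 for oxidative phosphorylation (reversed without stroma A replicate 3), and 0.00103 (without stroma B replicate 1) to 0.908 for immediate early and dissociation stress genes (reversed without stroma A replicate 3, and 0.888 without stroma B replicate 3). With 2 against 2 the reversed lists had 0.942 for A1 reactive, 0.566 for mature granule neuron, 0.9496 for TGF-beta, 0.538 for extracellular matrix and 0.414 for oxidative phosphorylation and ribosomal genes. With 1 against 3 they had 0.240 for A1 reactive, 0.912 for mature granule neuron, 0.247 for TGF-beta, 0.208 for inflammatory, 0.508 for extracellular matrix, 0.805 for oxidative phosphorylation and 0.198 for immediate early and dissociation stress genes, which had 0.951 with the Prm1 block. Id1 had log2 fold changes between −0.47 (without stroma B replicate 1) and 1.49 (without stroma B replicate 3), and −0.30 with 2 against 2.

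With the filter of 1000 genes and 5% mitochondrial UMIs, the astrocyte-like share was 0.286% in the primary and 0.494% in the relapsed library, the primary oligodendrocyte precursor-like share 0.680%, the relapsed myeloid share 0.232%, and the granule lineage 93.9% and 95.4%. With 200 genes and 20% the primary astrocyte-like share was 0.825%. Under the first naming rule the granule lineage was 70.8% and 88.8%, and the relapsed astrocyte-like and oligodendrocyte precursor-like shares were 1.32% and 0.0275%. Gfap in astrocyte-like cells had a log2 ratio of −0.61 with the stricter filter and 0.15 thinned. Other reversals were Cdc25c (−0.30) and Mki67 (−0.11) in the precursor class with doublets kept, Gli1 there with the stricter filter (0.0054), and Atoh1 in the differentiating class (−0.19 with 200 genes, −0.18 with doublets kept). The cause was not tested for these shares and ratios.

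Among other values, lists were unchanged in call and direction in 262 cases, passed newly in 24 and ceased to pass in 39. Named bulk genes were unchanged in 319, passed newly in 18 and ceased to pass in 263. Single-cell gene levels stayed within their intervals in 591 cases and moved outside them in 88, as did class shares in 142 and 47. The single-cell values rest on 1 library per group, so their intervals cover counting error only, and those of the astrocyte-like class rest on 54 and 65 cells.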

Other observations

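All values in this part were chosen after they had been seen, and no tests were run on them. The 20 unnamed cells of cluster 14.4, 0.234% of the primary library, carried the myelin gene Mbp at 5666 CPM, and also Gpr17 (1425) and Bmp4 (939), which mark committed oligodendrocyte precursors. The relapsed library had 0 such cells. In the same libraries the granule lineage had Bmp4 at 0.302 and 0.145 CPM.

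Gsto1 was among the named genes of both data types, with a log2 fold change of −4.35 in stroma B against stroma A and a log2 ratio of −4.86 in the precursor class of the relapsed against the primary library. The 2 comparisons share no libraries and stroma is not tied to a tumour, so the directions cannot be set side by side.

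The sorted libraries also differed in Y-linked reads. Ddx3y had 0, 666 and 844 reads in stroma A and 938, 0 and 1016 in stroma B, so libraries with and without them occur in both groups. Prm1 likewise had more than 1 read in 1 library of stroma A and in 2 of stroma B, whereas Prm2, the gene of the other protamine, had at most 5 in any library.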
